A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

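The series measured RNA of Schizosaccharomyces pombe by sequencing in 8 libraries: total RNA and polysome RNA of WT cells (strain yAS99) and of slr1- cells, a knockout, with 2 biological replicates per group per the labels. Cells grew in YES, a yeast extract medium, and cycloheximide was used. RNA was extracted with TRIzol, depleted of ribosomal RNA and made into stranded total RNA libraries, which were sequenced as single 50 bp reads. According to the submitters' processing notes the reads were aligned with Bowtie and quantified with RSEM, and the versions, options, genome build and annotation are not given in the sources used here.

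The deposited table of 527 genes is part of a longer table, and the rule by which its genes were chosen is not stated. In the deposited table each library has a count column, whose values are whole numbers. The deposited table also holds, per the file headers, log2 fold changes and p-values with false discovery rates for total RNA and for the translation test, a score for the direction of change, and ratios of polysome to total RNA and of slr1- to WT. It also gives a change type, "both" for 250 genes and "translational_only" for 277, with no other value. The 250 genes are those with a false discovery rate under 0.05 in total RNA. Each listed gene thus carries a label that may refer to translation. Whether the genes were chosen by this label is not stated. The authors' ratios of normalised polysome values were recomputed from the counts for 527 genes to within 0.005. Each of these ratios combines polysome and total counts of the same replicate number. The authors' log2 fold changes in total RNA were offset by -0.20 from the log2 ratio of the summed counts, and the rule behind that scale is not given. In the authors' translation test 0 genes had a false discovery rate under 0.05 (46 had a p under 0.05). Its p-values and rates imply an adjustment over at least 1194 genes, more than the 527 listed. Only the counts entered the tests made here. The totals over the listed genes were 802359 and 792679 (WT total RNA), 1110838 and 984147 (slr1- total RNA), 566241 and 550490 (WT polysome RNA), and 633394 and 666057 (slr1- polysome RNA). These totals cover the listed genes only and are not the depth of the libraries. Names, products, transcript lengths and untranslated regions came from the reference assembly ASM294v3, in which 515 of the 527 identifiers were found, all protein-coding. The identifiers with the prefix SPMIT, which marks the mitochondrial genome, have no name in the reference.

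The counts were fitted in edgeR 4.0.16 (R 4.3.3) with TMM scaling factors and a quasi-likelihood model with 1 mean per group over all 8 libraries (4 residual degrees of freedom, common dispersion 0.0127, biological coefficient of variation 0.113). Two-sided tests were made for slr1- against WT in total RNA, in polysome RNA and for the interaction, and for polysome against total RNA within each strain. All p-values were adjusted by Benjamini-Hochberg over the 527 genes, with a threshold of 0.05. No gene was removed by count, since the lowest mean was 161. Standard errors (SE) were derived from the test, as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Between replicates the SD of the log2 ratio over genes was 0.29 (WT total RNA), 0.28 (slr1- total RNA), 0.16 (WT polysome RNA) and 0.25 (slr1- polysome RNA). The chi-square of the replicates against counting noise alone was 13602, 11172, 3370 and 6839 on 526 degrees of freedom.

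Of 28 gene lists fixed before the data were examined, along with the groups, comparisons, settings and the rule for naming genes, 14 had at least 5 listed members and were tested, and 3 lists were added after the values had been seen. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01), again with the correlation estimated from the data, and with fry, each adjusted over the lists. Each comparison of the strains names 10 raised and 10 lowered genes, by size of the log2 fold change, from those past the threshold with a mean of at least 10 counts and no overlap between the libraries of the groups. Comparisons of polysome with total RNA name 5 in each direction. For each list described, up to 3 members past the threshold in each direction are named, or the member with the smallest p where none passed, and fewer in the within-strain comparisons and where a gene had been named already. Where no gene passed, the 5 with the smallest p are named as not past it.

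Alternatives tried were DESeq2 1.42.0, limma-voom, size factors from DESeq2, TMM factors computed without RP genes, library sizes alone, the authors' total RNA scale, fits on the compared groups only, on protein-coding genes, on genes of at least 500 counts, with RP gene copies summed or without SPMIT genes, replicate number as a block, a block or a ratio per pair of same-numbered total and polysome libraries for the interaction, which assumes a shared culture that the labels do not state, adjusted thresholds of 0.01 and 0.1, a 2-fold limit, and leaving out each library. The authors' scale, the limit of 500 counts, summed copies and leaving out SPMIT genes were added after the data had been seen. RP genes were compared with other genes matched on transcript length or mean count (5 matched genes for each RP gene, 10000 bootstrap draws, 95% interval), in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The procedure was tested on simulated data, in which it recovered 80.1% to 82.6% of planted 1.5-fold changes in the comparisons of 2 groups but 44.0% in the interaction, and 99.3% to 99.6% of 2-fold changes but 90.1% in the interaction. In the simulated data 200 of the 527 genes were changed, equally up and down and independently of each other. These shares need not hold for the real data, in which the RP genes moved together. With 2 libraries per group, neither other splits of the samples nor Dixon's test were used. The 12 identifiers not found in the reference were kept in the fits and left out of the length matching.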

Results

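Slr1p is the fission yeast homolog of LARP1, a La-related protein that binds mRNAs of the translation machinery in other organisms. RNA was compared between wild-type cells (WT, strain yAS99) and cells without Slr1p (slr1-), in total RNA and in polysome RNA, the mRNA bound by several ribosomes. Each of the 4 groups had 2 libraries, which the labels call biological replicates, so p-values measure the spread between these samples. Counts were used for 527 listed genes, with a lowest mean of 161 counts and a median of 627 counts per library. Ribosomal protein (RP) genes, 126 of the 527, held 45.5% and 45.3% of the listed counts in WT total RNA and 54.3% and 50.3% in slr1- total RNA. In polysome RNA their shares were 38.1% and 38.3% in WT and 42.1% and 43.2% in slr1-.

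The slr1 gene was not analysed here, so the absence of its transcript was not tested and the direction of every comparison rests on the sample labels. In the authors' deposited table, 250 of the listed genes had a false discovery rate under 0.05 in total RNA, and 245 of them were among the 281 genes that passed the test used here on the same counts.

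The comparison of slr1- with WT total RNA asked which mRNAs differ in abundance when Slr1p is absent. Of 527 genes, 281 passed the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment, 104 higher and 177 lower in slr1-. The largest rises among the genes named by the fixed rule were in pmp20, a peroxiredoxin gene (SPCC330.06c.1), and pgk1, the phosphoglycerate kinase gene (SPBC14F5.04c.1). The pmp20 mRNA rose 2.65-fold, from 607 ± 110 to 1606 ± 42.9 normalised counts (mean ± SD, n = 2 libraries per group; log2 1.40 ± 0.16 SE), and pgk1 rose 2.35-fold (1.23 ± 0.16). Of the other 8 raised genes 7 were RP genes, and ubi3, which is not in the RP list, encodes a fusion of ubiquitin with a ribosomal protein: rpl2101 (SPBC365.03c.1; 1.15 ± 0.16), rps1602 (SPAC664.04c.1; 1.04 ± 0.15), rpl1701 (1.01 ± 0.21), rpl3702 (0.95 ± 0.14), rps1201 (0.94 ± 0.12), rpl3602 (0.93 ± 0.11), rpp202 (0.92 ± 0.34) and ubi3 (0.83 ± 0.11). Several ribosomal protein genes have near-identical copies between which short reads are shared uncertainly, rpl1701 and rpl1702 among them, and rpl1702 did not pass (0.52 ± 0.21). The lowered genes were led by SPCC24B10.18 (-1.48 ± 0.26), the mitochondrial genome gene SPMIT.03 (-1.34 ± 0.28), the plasma membrane proton pump gene pma1 (SPAC1071.10c.1; -1.28 ± 0.27), SPMIT.08 (-1.19 ± 0.32) and the La homolog gene sla1 (SPAC57A10.10c.1; -1.18 ± 0.25). The next were the RNA polymerase subunit gene rpc10 (-1.18 ± 0.19), the cell wall glucosidase gene exg1 (-1.13 ± 0.20), ser1 of serine synthesis (-1.11 ± 0.22), the CTP synthase gene cts1 (-1.09 ± 0.15) and the translation initiation factor gene tif302 (SPAC25G10.08.1; -1.07 ± 0.14), which fell from 609 ± 19.6 to 290 ± 40.6 normalised counts. Of the 281 genes, 25 changed at least 2-fold, 5 upward and 20 downward. With genes of at least 500 counts 134 passed, 60 higher and 74 lower. The median log2 change of all genes was then -0.046, against -0.19 with all 527 genes.

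Without replicate 1 of slr1- total RNA, 127 genes passed, 51 higher and 76 lower. The calls of rpl1701 (0.68), rpp202 (0.55), SPMIT.03 (-1.09), pma1 (-1.05), SPMIT.08 (-1.25) and sla1 (-0.95) were then lost. The rpp202 call was also lost without replicate 1 of WT (0.55) or replicate 2 of slr1- (1.21), and with library sizes alone (0.73), DESeq2 (1.00), a replicate block (0.91) and genes of at least 500 counts (0.77). So was the SPMIT.08 call without replicate 2 of WT (-0.61) or replicate 2 of slr1- (-1.14), with DESeq2 (-1.12) and with TMM factors computed without RP genes (-0.85). In a fit that leaves a library out, the single library left in its group is assumed to vary like the libraries of the other groups.

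**Figure D1:**
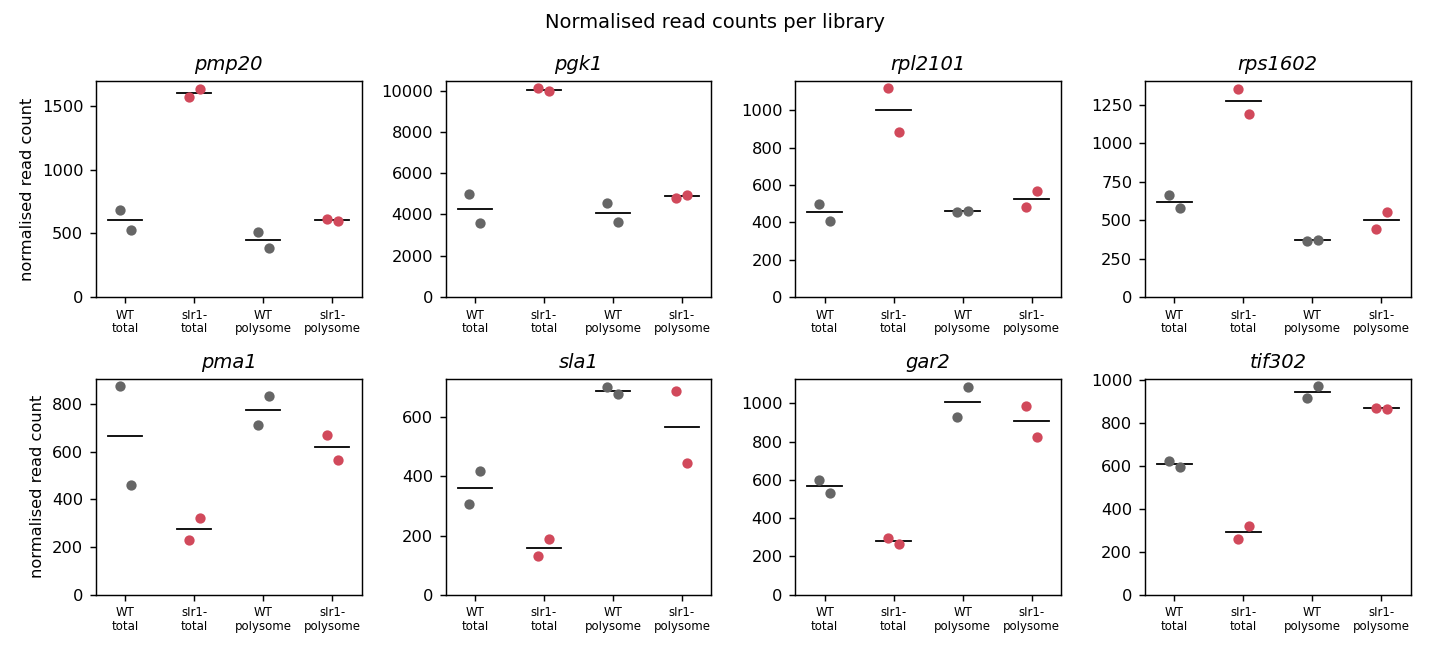
Normalised counts (y axis) of 8 genes in the 4 groups of libraries (x axis); dots are libraries, lines are group means, WT is grey and slr1- is red. In total RNA pmp20 rose 2.65-fold and pgk1 2.35-fold, whereas tif302 fell by 1.07 and pma1 by 1.28 on the log2 scale.

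The RP genes were the group with the broadest rise in total RNA. Of the 126 genes, 75 rose, 4 fell and 47 did not pass, against 76 and 4 adjusted over the list alone. Their median log2 change was 0.38, and 114 of the 126 values were positive. The camera test gave the list an adjusted p of 9.8e-34, and an adjusted p = 0.259 with an estimated correlation between genes. Large subunit genes (45 of 74 rose, 2 fell; 46 and 2 adjusted over the list alone; median 0.39) and small subunit genes (30 of 52 rose, 2 fell; the same numbers adjusted over the list alone; median 0.36) had camera adjusted p of 4.1e-18 and 1.5e-12 (adjusted p = 0.259 and 0.346 with an estimated correlation). Besides the genes above, rps1802 rose (0.80 ± 0.14). The 4 RP genes that fell were rps2202 (-0.79 ± 0.17), rpl39 (-0.75 ± 0.25), rpl3402 (-0.59 ± 0.19) and rps2601 (-0.36 ± 0.11). The call of rpl39 was lost without any 1 of replicate 1 of slr1- (-0.79), replicate 2 of slr1- (-0.70) and replicate 2 of WT (-0.35). That of rpl3402 was lost without replicate 1 of slr1- (-0.38) or of WT (-0.46), and that of rps2601 without replicate 2 of slr1- (-0.29) or of WT (-0.32). With TMM factors computed without RP genes the calls of rpl39 (-0.40), rpl3402 (-0.27) and rps2601 (-0.016) were lost. DESeq2 and its size factors in edgeR lost those of rpl39 (-0.67) and rps2601 (-0.28), and factors from the compared groups those of rpl3402 (-0.47) and rps2601 (-0.23). The other 401 listed genes had a median of -0.36, with 29 higher and 173 lower, so the RP median lay 0.74 above theirs. TMM factors computed without RP genes moved the median of all genes by 0.34, library sizes alone by -0.18 and factors from the compared groups alone by 0.13, while the RP median stayed 0.74 to 0.75 above that of the other genes. Other factors move all genes of a comparison nearly alike, so this difference could hardly change and is no test of the rise. The split of passing genes moved with the factors, to 182 higher and 72 lower without RP genes and to 60 higher and 260 lower with library sizes alone. Among the RP genes 107 were then higher and 1 lower (median 0.73) and 48 higher and 8 lower (median 0.20), respectively.

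Genes of ribosome biogenesis moved the other way from the RP genes. Of 16 genes, 14 fell, none rose and 2 did not pass (15 fell adjusted over the list alone), with a median of -0.75, and -0.41 with TMM factors computed without RP genes. The examples are gar1 (-1.05 ± 0.24), the nucleolin gene gar2 (SPAC140.02.1; -1.02 ± 0.15) and drs1 (-1.01 ± 0.18), which the reference annotates as an aspartate-tRNA ligase. By this annotation drs1 may not belong in the list. It is also counted among the aminoacyl-tRNA synthetase genes, and the counts and medians of this list include it. The camera test gave this list an adjusted p of 2.9e-04, with adjusted p = 0.346 with an estimated correlation. Of 26 translation factor genes, 10 fell, 1 rose and 15 did not pass (9 and 1 adjusted over the list alone). The examples are the initiation factor genes tif471 (-0.86 ± 0.25), int6 (-0.86 ± 0.14) and tif303 (-0.86 ± 0.14), which fell, and the elongation factor gene tef5 (0.47 ± 0.10), which rose. The median of the factors was -0.28 and turned to 0.06 with TMM factors computed without RP genes, and camera did not pass the list (adjusted p 0.107). It passed with genes of at least 500 counts (median -0.31), and fry passed the full list (adjusted p 0.0138). The median was -0.18 without replicate 2 of WT. Of the 5 genes of La, La-related and poly(A)-binding proteins and their partners, 4 fell and 1 did not pass (4 adjusted over the list alone; median -0.57; camera adjusted p 0.234, fry 0.0299). Their median was -0.20 without replicate 2 of WT and -0.87 without replicate 1 of WT. Besides sla1 these were lsm1 (-0.98 ± 0.21), lsm7 (-0.57 ± 0.20) and lsm6 (-0.50 ± 0.20), and the poly(A)-binding protein gene pabp did not pass (0.11 ± 0.12). With TMM factors computed without RP genes the calls of gar1 (-0.69), tif471 (-0.54) and lsm7 (-0.23) were lost and the La list had a median of -0.23, and lsm7 was also lost with DESeq2 and its size factors (-0.50). The tif471 call was lost without replicate 1 of slr1- (-0.48) or of WT (-0.83), and the lsm7 call without replicate 1 of slr1- (-0.56), replicate 2 of slr1- (-0.58) or replicate 2 of WT (-0.20). The sla1 call was lost without replicate 1 of slr1- (-0.95).

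Of 15 genes of glycolysis and fermentation 8 rose, none fell and 7 did not pass (8 adjusted over the list alone), with a median of 0.28 (0.098 with library sizes alone, 0.62 with TMM factors computed without RP genes) and 12 of 15 values positive. Camera gave this list an adjusted p of 0.00176, with adjusted p = 0.469 with an estimated correlation, and fry did not pass it (adjusted p 0.0515). The median was 0.18 without replicate 2 of WT, and the camera call was lost with genes of at least 500 counts (0.16). With pgk1, the alcohol dehydrogenase gene adh1 rose (0.76 ± 0.12). Of 16 respiration genes 6 fell and none rose (5 adjusted over the list alone), among them cox13 (-0.89 ± 0.18), atp15 (-0.88 ± 0.19) and sdh1 (-0.85 ± 0.18). Their median of -0.32 turned to 0.03 with TMM factors computed without RP genes and was -0.10 without replicate 2 of WT, and camera passed the list only without replicate 1 of WT (-0.38). Of 5 genes of the TCA cycle list 3 fell and none rose (4 adjusted over the list alone; median -0.65), among them aco1 (-0.54 ± 0.18) and mae1 (-0.83 ± 0.16), which is annotated as a malate transporter of the plasma membrane. Camera passed this list without replicate 2 of WT alone (median -0.92), and the median was -0.38 without replicate 1 of WT. Of 30 amino acid genes 9 fell and 2 rose (8 and none adjusted over the list alone), with pro3 (-0.89 ± 0.18) and his7 (-0.71 ± 0.17) beside ser1, and leu1 (0.39 ± 0.15) and ilv5 (0.33 ± 0.12) as the genes that rose. Of 12 purine and pyrimidine genes 4 fell and 1 rose (2 and none adjusted over the list alone), with ade3 (-0.78 ± 0.18), ura3 (-0.64 ± 0.17), ura1 (-0.57 ± 0.22) and ade2 (0.39 ± 0.14). The 12 genes include prs1, which is also counted among the aminoacyl-tRNA synthetase genes. Of 7 ergosterol genes 4 fell and none rose (4 adjusted over the list alone; median -0.61), among them hcs1 (-0.97 ± 0.17), erg28 (-0.81 ± 0.17) and erg9 (-0.74 ± 0.18). The medians of the amino acid list (-0.17) and the purine and pyrimidine list (-0.28) turned to 0.16 and 0.05 with TMM factors computed without RP genes. Those of the TCA (-0.65) and ergosterol lists (-0.61) were -0.32 and -0.28 with these factors. Without replicate 1 of slr1- the amino acid and purine and pyrimidine medians were -0.04 and -0.11, and without replicate 2 of slr1- the amino acid median was -0.38. Camera passed none of the TCA, amino acid, purine and pyrimidine and ergosterol lists with all libraries (adjusted p 0.0866, 0.329, 0.418 and 0.118). The fry test passed the TCA (adjusted p 0.0175) and ergosterol lists (0.0138). Without replicate 1 of slr1- the calls of atp15 (-0.88), aco1 (-0.37), leu1 (0.49), ilv5 (0.37), ade3 (-0.60), ura3 (-0.44) and ura1 (-0.29) were lost. Calls were also lost without replicate 1 of WT for aco1 (-0.38), ade2 (0.45), ura3 (-0.57) and ura1 (-0.39), without replicate 2 of WT for leu1 (0.24), ilv5 (0.23) and ade2 (0.34), and without replicate 2 of slr1- for leu1 (0.28), ilv5 (0.29) and ade2 (0.31). With TMM factors computed without RP genes the calls of aco1 (-0.21), ura3 (-0.31) and ura1 (-0.25) were lost, and with library sizes alone those of leu1 (0.21), ilv5 (0.15) and ade2 (0.21). Further calls were lost for aco1 with DESeq2 (-0.46) and factors from the compared groups (-0.41), for leu1 and ade2 with a replicate block (0.40 and 0.39), and for leu1 (0.25) and ilv5 (0.19) with genes of at least 500 counts. The ura1 call was lost with DESeq2 size factors (-0.50), protein-coding genes only (-0.53), SPMIT genes left out (-0.53), RP copies summed (-0.54) and the authors' scale (-0.57).

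Of 12 chaperone genes 3 fell and 1 rose (the same numbers adjusted over the list alone). These were pdi1 (-0.74 ± 0.22), mas5 (-0.71 ± 0.15) and sks2 (-0.32 ± 0.10), which fell, and hsp10 (0.40 ± 0.13), which rose. Their median of -0.32 turned to 0.02, and the value of sks2 to 0.018, with TMM factors computed without RP genes. Of 6 core stress genes 1 rose, tdh1 (0.59 ± 0.11; 1 adjusted over the list alone), and the median of 0.04 turned to -0.15 with library sizes alone and was 0.18 without replicate 2 of WT. Camera passed neither list (adjusted p 0.280 and 0.234), except the chaperones with genes of at least 500 counts (median -0.46). The chaperone median was -0.12 without replicate 1 and -0.52 without replicate 2 of slr1-. The calls of hsp10 (0.32), pdi1 (-0.44) and sks2 (-0.29) were lost without replicate 1 of slr1-, and without replicate 1 of WT (0.35, -0.67 and -0.24). Those of pdi1 (-0.42) and mas5 (-0.37) were lost with TMM factors computed without RP genes, and that of hsp10 with library sizes alone (0.22) and genes of at least 500 counts (0.26). That of sks2 was lost with DESeq2 and its size factors (-0.24) and factors from the compared groups (-0.19). Of the 14 fixed lists tested, camera passed 5 in total RNA, and 0 held their call with an estimated correlation in this or any other comparison. The fry test, which asks whether the genes of a list move on balance in one direction, passed 8 lists in total RNA, the RP (adjusted p 0.0138) and ribosome biogenesis lists (0.00848) among them.

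In polysome RNA no single gene passed between slr1- and WT. The count was 0 with the edgeR quasi-likelihood test, against 100 genes at an unadjusted p under 0.05, 27 genes with DESeq2 and 0 with limma-voom, and 2 genes passed without replicate 1 of slr1- polysome RNA. The 5 genes with the smallest p, none past the threshold, were the translation-associated gene tma19 (0.55 ± 0.11), rps1502 (0.62 ± 0.13), rpl3202 (0.51 ± 0.11), the transcription factor gene sfp1 (-0.68 ± 0.15) and the Hsp90 co-chaperone gene aha1 (SPBC1711.08.1; 0.61 ± 0.14). Of the 100 genes at an unadjusted p under 0.05, 71 had higher values in slr1-, 55 of them RP genes, and 29 had lower values, with 0 RP genes. The RP list had a median of 0.27 (1.21-fold), with 119 of 126 values positive. Adjusted over the list alone, 30 RP genes were higher and 0 lower, whereas over all genes 0 passed. The camera test gave the RP list an adjusted p of 1.4e-31, with adjusted p = 0.295 with an estimated correlation, and fry did not pass it (adjusted p 0.0913). The small subunit genes had a median of 0.30 (19 higher adjusted over the list alone, 0 over all genes; camera adjusted p 1.7e-15) and the large subunit genes 0.24 (2 and 0; 6.0e-14), both with adjusted p = 0.295 with an estimated correlation. With library sizes alone the RP median was 0.18 and the large subunit median 0.15. The other 401 genes had a median of -0.09, which placed the RP median 0.36 above theirs. The TCA cycle list had a median of -0.36 (camera adjusted p 0.00619, adjusted p = 0.531 with an estimated correlation), and its member with the smallest p was sdh1 (-0.48 ± 0.20), not past the threshold. Camera passed 2 further lists only when a library was left out, respiration without replicate 1 of WT polysome RNA (median -0.18) or replicate 1 of slr1- polysome RNA (-0.19), and amino acid synthesis without replicate 2 of either (-0.13 each). The respiration median with all libraries was -0.06 and turned to 0.0020 with TMM factors computed without RP genes.

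The changes in total and polysome RNA, which come from separate libraries, ran in the same direction for 77.8% of the 527 genes (Pearson correlation of the log2 changes 0.63, Spearman 0.65). The slope of the polysome change on the total change was 0.32. Noise in the total RNA changes lowers such a slope, so it does not measure how much smaller the polysome changes were. The SD of the log2 changes over all genes was 0.51 in total RNA and 0.26 in polysome RNA. Genes are not independent replicates, and the correlation was 0.46 for the non-RP genes and 0.28 for the RP genes. Of the genes that passed as raised in total RNA, 43 had an unadjusted p under 0.05 with a higher value in polysome RNA. Of the lowered genes, 17 had one with a lower value. Chance over all genes gives 14.0 and 9.74. These chance values do not allow for the RP genes, which were 75 of the 104 raised genes and 55 of the 71 higher in polysome RNA. The 43 genes thus do not separate agreement gene by gene from higher RP values in both kinds of RNA.

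**Figure D2:**
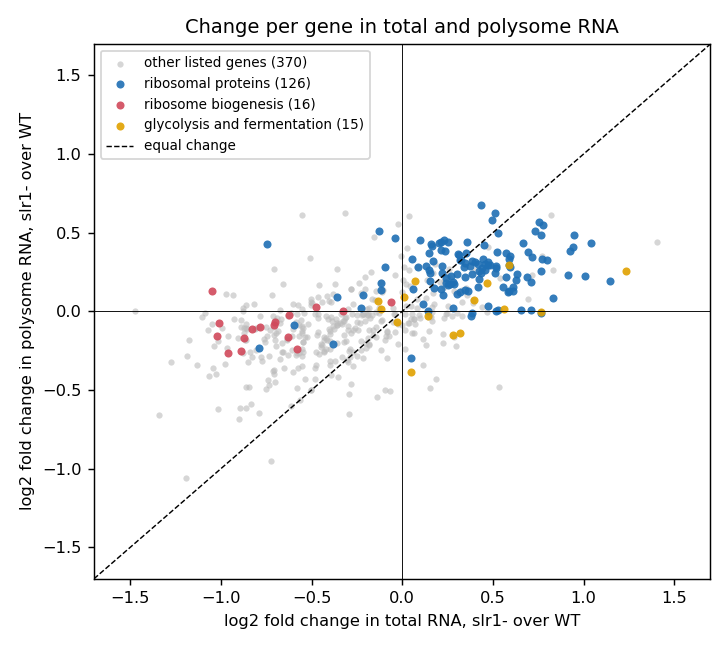
Log2 change between slr1- and WT in total RNA (x axis) and in polysome RNA (y axis), 1 point per gene, for 126 RP genes (blue), 16 ribosome biogenesis genes (red), 15 glycolysis genes (yellow) and 370 other genes (grey), with a dashed line of equal change. The RP genes had medians of 0.38 in total and 0.27 in polysome RNA, and the correlation over all genes was 0.63.

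The interaction asked whether the change between strains differed between polysome and total RNA. With the edgeR quasi-likelihood test 2 genes passed after Benjamini-Hochberg adjustment, against 140 at an unadjusted p under 0.05, 37 with DESeq2 and 0 with limma-voom. The aha1 mRNA rose in polysome relative to total RNA in slr1- (1.17 ± 0.20, 2.24-fold), with 454 ± 22.8 and 693 ± 34.0 normalised counts in WT and slr1- polysome RNA and 375 ± 41.5 and 255 ± 12.8 in total RNA. The mitochondrial genome gene SPMIT.10 (SPMIT.10.1) fell in the same comparison (-1.01 ± 0.15), with 7063 ± 201 and 10208 ± 919 in total RNA and 356 ± 0.0949 and 255 ± 0.854 in polysome RNA. These polysome SDs lie far below the counting noise at such counts, so they do not measure the precision of the values. The next genes in order of p, none past the threshold, included rpl14 (-0.74 ± 0.16), adh1 (-0.77 ± 0.17), mas5 (0.98 ± 0.21), gar2 (0.86 ± 0.21) and hcs1 (1.08 ± 0.24). The RP list had a median of -0.13, with 85 of 126 values negative and 0 genes past the threshold over all genes or adjusted over the list alone. This median was -0.41 with TMM factors computed without RP genes and -0.045 with library sizes alone. Relative to the other listed genes the RP median was -0.37, and -0.37 to -0.38 under the other scalings, which move all genes nearly alike and so could hardly change it. The camera test gave the RP list an adjusted p of 1.9e-10, with adjusted p = 0.599 with an estimated correlation, and fry did not pass it (adjusted p 0.429). With a library left out the RP median ran from -0.22 (replicate 2 of WT polysome RNA) to -0.06 (replicate 1 of slr1- total RNA). The large subunit median was -0.18 (camera adjusted p 2.0e-08, adjusted p = 0.599 with an estimated correlation; 1 gene higher and 3 lower adjusted over the list alone, 0 over all genes). Without replicate 1 of slr1- total RNA the large subunit median was -0.09, and it was -0.46 with TMM factors computed without RP genes and -0.087 with library sizes alone. The small subunit median of -0.069 (camera adjusted p 0.00120, adjusted p = 0.693 with an estimated correlation) turned to 0.02 with library sizes alone and was -0.36 with TMM factors computed without RP genes, and its call was lost without replicate 1 of slr1- total RNA (0.04) and with genes of at least 500 counts (-0.03). The ribosome biogenesis list had a median of 0.64 with 16 of 16 values positive (camera adjusted p 9.0e-05, adjusted p = 0.599 with an estimated correlation; 9 genes higher adjusted over the list alone, 0 over all genes). This median was 0.40 without replicate 1 of slr1- polysome RNA and 0.37 with TMM factors computed without RP genes, and fry did not pass the list (adjusted p 0.0541). The fall of this list in total RNA (median -0.75) enters the interaction with the opposite sign, so these results are not independent. The glycolysis list had a median of -0.30 (camera adjusted p 1.6e-04, adjusted p = 0.692 with an estimated correlation; 3 genes lower adjusted over the list alone, 0 over all genes), and -0.58 with TMM factors computed without RP genes. The fry test passed 0 of the 14 fixed lists in the interaction (adjusted p 0.314 for the large subunit and glycolysis lists, 0.529 for the small subunit list). For the purine and pyrimidine list the median was positive (0.22, and -0.043 with TMM factors computed without RP genes) while camera ranked it as lower. Camera also passed the chaperone list without replicate 2 of WT total RNA (median 0.41), and the chaperone (0.32) and translation factor (0.26) lists with genes of at least 500 counts. The translation factor median over all counts, 0.25, turned to -0.016 with TMM factors computed without RP genes.

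The number of interaction genes moved with single libraries. It was 32 without replicate 1 of WT total RNA, 5 without replicate 2 of WT total RNA and 77 without replicate 2 of slr1- total RNA. It was 0 without replicate 1 of slr1- total RNA, replicate 1 of WT polysome RNA or either slr1- polysome library, and 3 without replicate 2 of WT polysome RNA. The aha1 call was lost without replicate 1 of slr1- total RNA (1.11), replicate 1 (1.22) or 2 (1.01) of WT polysome RNA and replicate 1 (0.99) or 2 (1.17) of slr1- polysome RNA. The SPMIT.10 call was lost without replicate 1 of slr1- total RNA (-0.92), replicate 1 of WT polysome RNA (-1.01) and replicate 1 (-1.13) or 2 (-1.05) of slr1- polysome RNA. Both calls were lost with TMM factors computed without RP genes (0.89 and -1.30) and limma-voom (1.16 and -1.01), and that of aha1 with protein-coding genes only (1.12) and SPMIT genes left out (1.12). Library sizes alone gave 31 interaction genes (25 higher, 6 lower), and TMM factors computed without RP genes moved the median of all genes by -0.27 and gave 0.

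Within WT, polysome RNA was compared with total RNA, which shows which mRNAs were relatively enriched on polysomes. Of 527 genes 262 passed, 110 higher and 152 lower in polysome RNA. The highest were the initiation factor gene tif5 (1.24 ± 0.18), fil1 (1.21 ± 0.18), pac2 (1.21 ± 0.17), rpl3402 (1.19 ± 0.18) and sfp1 (1.10 ± 0.16). The lowest were all of the mitochondrial genome: SPMIT.07 (-4.56 ± 0.21), SPMIT.10 (-4.31 ± 0.12), SPMIT.08 (-4.09 ± 0.39), SPMIT.11 (-3.72 ± 0.17) and SPMIT.04 (-3.46 ± 0.18). Of the RP genes 70 were lower, 7 higher and 49 did not pass (72 and 7 adjusted over the list alone), with rps21 (-2.31 ± 0.15), rps1702 (-2.29 ± 0.12) and rpl4302 (-1.84 ± 0.17) at the bottom. Their median of -0.37 lay at -0.50 relative to the other genes (camera adjusted p 3.8e-08, adjusted p = 0.775 with an estimated correlation). With library sizes alone 44 RP genes were lower and 26 higher, and their median was -0.055. The large subunit median (-0.30) turned to 0.02 with library sizes alone, and the small subunit median of -0.51 was then -0.19. Of 16 ribosome biogenesis genes 9 were higher and 2 lower (9 and 3 adjusted over the list alone), with gar2 (0.84 ± 0.15) and fib1 (-1.27 ± 0.25) as examples and a median of 0.51 (0.82 with library sizes alone). Camera did not pass this list (adjusted p 0.0801) except without replicate 2 of WT total RNA (median 0.44) and with TMM factors computed without RP genes (0.40). Of 26 translation factor genes 7 were higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p 0.0931), with tif471 (1.06 ± 0.24) and tma19 (-1.14 ± 0.11) as examples. The chaperone genes ssc1 (-1.99 ± 0.16) and bip1 (-1.81 ± 0.20) and the respiration genes sdh1 (-1.56 ± 0.19) and atp2 (-1.33 ± 0.14) were also lower. Camera passed neither of their lists (adjusted p 0.983 and 0.606), in which 3 chaperone genes were higher and 4 lower, and 2 respiration genes higher and 5 lower (the same numbers adjusted over the list alone). The count was 163 without replicate 1 of WT polysome RNA. Library sizes alone moved the median of all genes by 0.32 and gave 246 higher and 104 lower genes, and TMM factors computed without RP genes gave 79 higher and 166 lower.

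Within slr1-, 341 genes passed between polysome and total RNA, 179 higher and 162 lower. The highest were tif5 (1.89 ± 0.19), sla1 (1.84 ± 0.24), gar1 (1.82 ± 0.24), cdb4 (1.77 ± 0.18) and nap1 (1.76 ± 0.20), and the lowest were SPMIT.10 (-5.32 ± 0.12), SPMIT.07 (-4.92 ± 0.22), SPMIT.11 (-4.36 ± 0.17), SPMIT.08 (-3.96 ± 0.43) and SPMIT.04 (-3.64 ± 0.19). Of the RP genes 83 were lower, 5 higher and 38 did not pass (85 and 5 adjusted over the list alone), with rps1702 (-2.31 ± 0.12) and rps21 (-2.22 ± 0.15) again low. Their median was -0.52, and -0.77 relative to the other genes (camera adjusted p 4.4e-15, adjusted p = 0.498 with an estimated correlation). With library sizes alone 49 RP genes were lower and 24 higher, and their median was -0.11, against -0.91 with TMM factors computed without RP genes. Of 16 ribosome biogenesis genes 13 were higher and 1 lower (the same numbers adjusted over the list alone), with a median of 0.94, and 0.57 with TMM factors computed without RP genes (camera adjusted p 0.00143, adjusted p = 0.498 with an estimated correlation). The lower gene, fib1 (-0.65), lost its call without replicate 1 of slr1- total RNA (-0.14) or replicate 2 of slr1- polysome RNA (-0.48), with library sizes alone (-0.24) and with limma-voom (-0.61). Of 26 translation factor genes 14 were higher and 3 lower (the same numbers adjusted over the list alone), with int6 (1.36 ± 0.14) and tif471 (1.31 ± 0.25) as examples. Their median of 0.38 turned to -0.01 with TMM factors computed without RP genes, and the camera call (adjusted p 0.0494, adjusted p = 0.697 with an estimated correlation) was lost without replicate 1 (median 0.18) or 2 (0.43) of slr1- polysome RNA. It was also lost with these factors, a replicate block (0.38), RP copies summed (0.34), the authors' scale (0.37) and the compared groups only (0.38). Of 15 glycolysis genes 7 were lower and 2 higher (7 and 1 adjusted over the list alone), with pgk1 (-1.04 ± 0.15) and eno101 (-1.05 ± 0.20), and their median of -0.27 turned to 0.14 with library sizes alone. Library sizes alone moved the median of all genes by 0.41 and gave 292 higher and 94 lower genes. TMM factors computed without RP genes moved it by -0.37 and gave 100 higher and 246 lower genes.

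**Figure D3:**
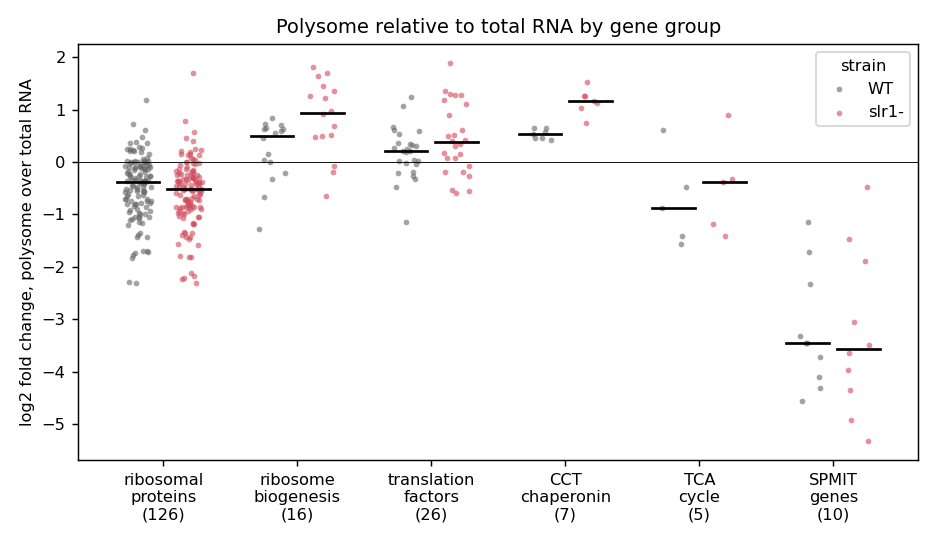
Log2 change of polysome over total RNA (y axis) for 6 groups of genes in WT (grey) and slr1- (red); dots are genes and lines are group medians. The RP medians were -0.37 and -0.52 and those of ribosome biogenesis 0.51 and 0.94, while in slr1- the medians of the TCA cycle (-0.37) and of translation factors (0.38) turned to 0.03 and -0.01 under another scaling.

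A planned search for pyrimidine runs near the 5' end of the mRNAs was void where RP genes were included. The reference annotates a 5' untranslated region of at least 20 nt for 50.0% of the RP genes and 75.9% of all listed genes. Among the other genes 84.0% had one. Without RP genes, the share with a run of at least 7 pyrimidines did not differ past the threshold between higher or lower genes and those that did not pass. This held in total RNA and in polysome against total RNA of each strain (Fisher's exact test, adjusted p 0.268 to 0.722). Annotated starts may differ from the real ones.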

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

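Summing the RP copies and testing the CCT chaperonin list were chosen after the results had been seen. The predictions of the other tests of explanations were written before those tests, but for patterns already found in the results. The interaction, which tests whether the strains differ by another amount in polysome than in total RNA, passed its threshold for 2 genes and 6 lists. SPMIT.10 had an interaction of -1.01 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p 0.0221) and aha1 one of 1.17 (adjusted p 0.0353). These p-values were adjusted over the 527 listed genes only. The authors' translation test was adjusted over at least 1194 genes, so its 0 genes cannot be set against these 2. Whether the 2 genes would pass over a larger set was not tested. By camera the lists were RP genes (median -0.13, adjusted p 1.9e-10), large subunit RP genes (-0.18, 2.0e-08), small subunit RP genes (-0.069, 0.00120), ribosome biogenesis (0.64, 9.0e-05), glycolysis and fermentation (-0.30, 1.6e-04) and CCT chaperonin (0.68, 0.00231). None of these 6 lists passed with a correlation estimated from the data (adjusted p 0.599 to 0.700), and fry passed none (0.0541 to 0.529). With TMM factors computed without RP genes the medians were -0.41, -0.46, -0.36, 0.37, -0.58 and 0.40 in that order, and with library sizes alone those of the RP lists were -0.045, -0.087 and 0.02. The small subunit call was lost without replicate 1 of slr1- total RNA (0.04), and 0 to 77 genes passed when 1 library was left out, with 0 without replicate 1 of slr1- total RNA and 77 without replicate 2.

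The higher RP mRNAs in slr1- total RNA were weighed against transcript length, abundance and a single deviating library. Against other genes of the same transcript length the RP median was higher by 0.55 (95% interval 0.466 to 0.732), and against genes of the same mean count by 0.41 (0.309 to 0.524). Without matching the difference was 0.74, so it was smaller after each matching but did not vanish. The intervals draw genes, not libraries, and do not measure the spread between replicates. In simulated data with a trend alone, the interval held 0 in 17 of 20 runs for transcript length and in 19 of 20 for mean count. Over the 4 pairs of 1 slr1- and 1 WT library the difference of medians ran from 0.505 to 0.973, which argues against 1 deviating library as the whole source. Reads shared between RP gene copies were addressed by summing the copies, which left the median at 0.42. The absence of Slr1p stays open as a biological hypothesis that may explain the rise, and a difference in growth between the strains was not tested.

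The smaller RP change in polysome than in total RNA was weighed in the same way. Matched on transcript length, the interaction of RP genes differed from that of the others by -0.36 (-0.463 to -0.217), and matched on mean count by -0.14 (-0.240 to -0.0460). The difference without matching was -0.37, so matching on mean count made it smaller. These intervals, too, draw genes and not libraries. Over the 16 choices of 1 library per group the difference of medians ran from -0.606 to -0.0962, so no single library accounts for its sign. The interaction uses the same total RNA libraries as the total RNA comparison, so a deviation in these moves the 2 results in opposite directions, and without replicate 1 of slr1- total RNA the RP median was -0.06. The values leave open whether the difference follows from the absence of Slr1p or from polysome libraries in which all changes are smaller. Over the non-RP genes the SD of the log2 changes was 0.43 in total RNA and 0.23 in polysome RNA. These SDs also hold noise. The RP median lay 0.74 and 0.36 above that of the other genes, so both measures were smaller in polysome RNA by similar proportions.

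The lower SPMIT.10 in slr1- polysome relative to total RNA was weighed against different carry-over of mitochondria into the polysome fractions. The prediction was that carry-over would move the 10 SPMIT genes alike. Their interactions ran from -1.01 to 0.68, with 5 below and 5 above 0. A chi-square test of equal values gave 46.9 on 9 degrees of freedom (p 4.0e-07, from the standard errors derived from the F statistics). This test cannot decide on carry-over, since it includes SPMIT.10, which was picked for its value. The interaction also subtracts total RNA changes, which ran from -1.34 to 0.53 over these genes. A shared shift in polysome RNA alone could thus give unequal interactions. A shared carry-over and a biological difference between the strains both stay open as hypotheses. The call was lost without replicate 1 of slr1- total RNA (-0.92), replicate 1 of WT polysome RNA (-1.01) and replicate 1 (-1.13) or 2 (-1.05) of slr1- polysome RNA. The change of aha1 was not weighed.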

How the results depend on the processing

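The alternatives with genes of at least 500 counts, RP copies summed, SPMIT genes left out and the authors' total RNA scale were chosen after the data had been seen. In total RNA, 281 genes passed, and 134 with genes of at least 500 counts, 162 at 0.01, 25 at 2-fold and 127 to 288 with 1 library left out (127 without replicate 1 of slr1-). In polysome RNA 0 passed by edgeR (100 at an unadjusted p under 0.05), against 27 by DESeq2, 0 by limma-voom, 17 at 0.1 and 0 to 2 with a library left out (2 without replicate 1 of slr1-). The interaction count of 2 became 31 with library sizes alone, 37 by DESeq2, 9 with a replicate block, 46 with a block and 13 with ratios that take the same-numbered total and polysome libraries of a strain as pairs, 13 with genes of at least 500 counts, 4 with copies summed and 55 at 0.1. It became 0 with TMM factors computed without RP genes, limma-voom, protein-coding genes only, SPMIT genes left out and a threshold of 0.01 (140 at an unadjusted p under 0.05), and 0 to 77 with a library left out (77 without replicate 2 of slr1- total RNA). Polysome against total RNA gave 262 genes in WT (160 with genes of at least 500 counts, 161 at 0.01, 76 at 2-fold, and 163 to 228 with a library left out, 163 without replicate 1 of WT polysome RNA) and 341 in slr1- (197, 273, 130, and 277 to 339). The correlation of total and polysome changes was 0.63, 0.460 without RP genes and 0.525 to 0.663 with a library left out. The RP median held its camera call in each fit with a library left out, at 0.32 to 0.45 in total RNA, 0.22 to 0.26 in polysome RNA and -0.22 to -0.06 in the interaction. It missed the threshold with an estimated correlation (0.38, adjusted p 0.259; 0.27, 0.295; -0.13, 0.599) and in polysome RNA and the interaction also with fry (0.27, 0.0913; -0.13, 0.429). The direction of 4 named genes turned with the scaling: sks2 in total RNA to 0.018 with TMM factors computed without RP genes, and tdh1 to 0.061, grx1 to 0.10 and gua1 to 0.11 in slr1- polysome against total RNA with library sizes alone. A replicate block gave 274, 0, 9, 246 and 337 genes in the 5 comparisons and RP medians of 0.38, 0.27 and -0.14. The authors' polysome ratios combine libraries of the same replicate number, but whether these come from the same culture is not stated. Replicate differences correlated at -0.29 to 0.29 between groups, and at 0.29 in WT and 0.070 in slr1- between total and polysome RNA of 1 strain. Stricter thresholds lower counts by construction, and for the other changes the cause was not tested. Of 56 genes named in total RNA, 32 kept their call in each alternative, as did 46 of 67 in slr1- polysome against total RNA, while both interaction genes lost theirs in some. Filters at 0 or 50 counts removed no gene and were void, and settings for pseudocounts and for the authors' table alone were not run. The pyrimidine search with RP genes was void at each run length and window. Without RP genes no run length or window gave an unadjusted p under 0.05 by Fisher's exact test.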

Other observations

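The lists of CCT chaperonin, aminoacyl-tRNA synthetase and mitochondrial genome genes, and the genes of organelle proteins named here, were chosen after the values had been seen. All 7 CCT chaperonin genes fell in slr1- total RNA (median -0.81, camera adjusted p 0.00522, adjusted p = 0.518 with an estimated correlation), from cct4 (-0.99) to cct3 (-0.41). The median was -0.48 with TMM factors computed without RP genes. Their interaction median was 0.68, with 5 genes adjusted over the list alone and 0 over all genes (camera adjusted p 0.00231, adjusted p = 0.700 with an estimated correlation). It was 0.40 with TMM factors computed without RP genes, and fry did not pass the list (adjusted p 0.138). In polysome RNA their median was -0.11 (-0.20 without replicate 1 and -0.06 without replicate 2 of slr1- polysome RNA, -0.21 with library sizes alone), and camera did not pass the list (adjusted p 0.202). All 7 were higher in polysome than in total RNA, with medians of 0.54 in WT and 1.16 in slr1- (camera adjusted p 0.00552 and 0.00116, adjusted p = 0.706 and 0.550 with an estimated correlation). These medians were 0.85 and 1.56 with library sizes alone, and 0.43 and 0.79 with TMM factors computed without RP genes. The interaction and the slr1- polysome-to-total values subtract the same slr1- total RNA libraries in which the list fell. They are therefore not separate support for that fall. The same holds for the aminoacyl-tRNA synthetase list below.

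Of 17 aminoacyl-tRNA synthetase genes, 8 fell in slr1- total RNA and none rose (median -0.48, camera adjusted p 0.0222, adjusted p = 0.640 with an estimated correlation). The median was -0.15 with TMM factors computed without RP genes, and fry did not pass the list (adjusted p 0.0550). The camera call was lost without replicate 1 of WT (-0.45), without replicate 1 of slr1- (-0.27) and with RP copies summed (-0.44). In polysome RNA the median was -0.16 (camera adjusted p 0.0113, adjusted p = 0.704 with an estimated correlation), fry did not pass the list, and the camera call was lost without replicate 1 of slr1- polysome RNA (-0.14), while the median was -0.28 without replicate 2. In polysome against total RNA 5 genes were higher in WT and 11 in slr1- (1 and 11 adjusted over the list alone), with medians of 0.32 and 0.65 (camera adjusted p 0.00737 and 0.00716, adjusted p = 0.736 and 0.816 with an estimated correlation), and fry did not pass the list in WT (adjusted p 0.170). The medians were 0.64 and 1.06 with library sizes alone, and 0.22 and 0.28 with TMM factors computed without RP genes. The interaction of the list passed camera only without replicate 2 of slr1- total RNA (0.51).

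The 10 SPMIT genes held 4.52% and 5.63% of the listed counts in WT total RNA and 3.98% and 4.43% in slr1- total RNA, against 0.521%, 0.579%, 0.448% and 0.309% in the polysome libraries. All 10 were lower in polysome than in total RNA in WT (median -3.45) and 9 in slr1- (-3.56). In slr1- total RNA 5 fell and SPMIT.10 rose (0.53 ± 0.10; median -0.52, or -0.18 with TMM factors computed without RP genes, camera adjusted p 0.418). In polysome RNA their median was -0.49 (camera adjusted p 2.5e-05, adjusted p = 0.516 with an estimated correlation; 3 lower adjusted over the list alone, 0 over all genes). This median was -0.79 without replicate 1 and -0.26 without replicate 2 of slr1- polysome RNA, and fry did not pass the list (adjusted p 0.261). The interaction of this list had a median of 0.05 (-0.23 with TMM factors computed without RP genes, -0.026 with DESeq2 size factors) and a mean of -0.05, and it passed camera only without replicate 2 of WT total RNA (-0.21) or replicate 1 of slr1- polysome RNA (-0.67). Without replicate 2 of slr1- polysome RNA the median was 0.31.

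Some nuclear genes of proteins of the endoplasmic reticulum and mitochondria, picked for their low values, were lower in polysome than in total RNA in WT and slr1-: pdi2 (-2.34 and -2.34), ssc1 (-1.99 and -1.92), ilv3 (-1.85 and -1.81), bip1 (-1.81 and -1.57), cnx1 (-1.61 and -1.30), sdh1 (-1.56 and -1.19) and atp2 (-1.33 and -1.21). No list of such genes was tested. The fixed respiration list was mixed, with 2 genes higher and 5 lower in WT, and 3 higher and 5 lower in slr1-, where 11 of 16 values were positive and the median (0.14) and mean (-0.07) differed in sign, the median turning to -0.24 with TMM factors computed without RP genes. With library sizes alone, which moved the median of all genes by 0.32 in WT and 0.41 in slr1-, ssc1 had -1.67 and -1.52 and atp2 -1.01 and -0.81.

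In replicate 1 of WT total RNA the lowest count was 256, and 41 genes lay within 10% above it, against 1, 2 and 3 genes within 10% above the minimum of the other total RNA libraries. That library may therefore have been used to choose the listed genes. Such a choice could raise its counts near the limit, which would make genes there look lower in slr1- total RNA. With genes of at least 500 counts the excess of lowered genes was smaller (60 higher and 74 lower, against 104 and 177). The scaling factors were computed anew on these genes, and the median of all genes moved from -0.19 to -0.046. RP genes have high counts (median 2135, against 627 for all genes) and weigh more in that fit. The smaller excess thus cannot be told apart from a change of scale. The RP difference matched on mean count had a lower bound of 0.309. That mean is over all libraries, so the matching does not test a choice made on 1 library.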
